A study of Mus musculus with 15 samples.

How the data were processed

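RNA-seq libraries of mouse plasma cells were compared between 5 sorted groups with 3 biological replicates each: spleen B220+2NBDG-, B220-2NBDG-, B220+2NBDG+ and B220-2NBDG+, and bone marrow plasma cells (BMPC). Per the labels, about 30000 cells of each subset were double sorted from male C57Bl6/N mice aged 8 to 12 weeks. RNA was isolated with a Macherey-Nagel NucleoSpin XS kit, cDNA was made with Clontech SMART-seq, and libraries were made with Nextera. Transcripts were quantified by the authors with Salmon 0.9.1 against GRCm38.p6. Versions of other tools used on the reads are not given in the sources used here.

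The deposited table holds TPM (transcripts per 1000000) by the authors for 63553 Ensembl transcripts in 15 library columns, each of which sums to 1000000. Its other values are the deposited length and effective length of each transcript in nt, which per the file headers belong to no sample. The effective length is the length minus 249 for 96.4% of transcripts. Transcripts were assigned to 22339 genes with GENCODE M21, which lists 99.7% of them, 96.4% in the same version. Estimated reads per transcript were recovered from TPM and effective length, since products for transcripts of at least 500 nt with at most 20 reads came out within 0.05 of a whole number in 71.4% to 74.0% of cases once scaled. They put the depth at 17290257 to 24876424 reads per library, and at 4407070 to 9916079 outside the immunoglobulin genes.

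TPM was summed per gene. Immunoglobulin locus genes (262) were removed for gene tests and the remaining TPM rescaled to 1000000 per library, which multiplied the values of other genes by 11.2 to 29.3. TPM in the text is on this main scale unless called deposited. Genes with at least 1 TPM in at least 3 of the 15 libraries were tested (11246 genes), on log2(TPM + 1). One limma 3.58.1 model of the 5 group means was fitted with lmFit, contrasts.fit and eBayes with a trend, in R 4.3.3, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each of 8 comparisons. These were 2NBDG+ against 2NBDG- averaged over B220 and within each B220 stratum, B220- against B220+ averaged over 2NBDG and within each 2NBDG stratum, the interaction of 2NBDG and B220, and BMPC against spleen B220-2NBDG+, which share the B220- 2NBDG+ phenotype. The groups, comparisons, tests, gene lists and rule for named genes were set before the data were examined.

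Each of 31 gene lists was tested with camera (limma) at a preset correlation of 0.01 and, beside it, with an estimated correlation. Values were adjusted over the lists within each of 4 comparisons (2NBDG averaged, B220 averaged, interaction and bone marrow), and called members were counted over all tested genes and adjusted over the list alone. The metabolic lists were glucose transport and glycolysis, pyruvate import and TCA cycle, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, fatty acid oxidation, cholesterol biosynthesis, hexosamine pathway and N-glycosylation, amino acid transport and ATF4 targets, and oxidative stress defence. Those of secretion and growth were the unfolded protein response and ER chaperones, secretory translocon and COPII and COPI transport, autophagy and lysosome, cell cycle, MYC targets and ribosome biogenesis, and cytosolic ribosomal proteins. Those of identity and signalling were B cell identity, MHC class II presentation, plasma cell identity, BCL2 family and cell survival, homing adhesion and chemokine receptors, NF-kappaB pathway and targets, interferon response, and immediate early and heat shock genes. Markers of other cells covered T cells, NK cells, neutrophils, monocytes with macrophages and dendritic cells, erythroid cells, megakaryocytes and platelets, mast cells with basophils and eosinophils, and stromal with endothelial cells.

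Genes were named by a rule. For the averaged 2NBDG, averaged B220 and bone marrow comparisons it took the 8 highest and 8 lowest log2 fold changes among called genes with at least 10 TPM in a group and libraries that did not overlap, within each stratum for averaged comparisons. Immunoglobulin and T cell receptor genes, unnamed gene models and pseudogenes were left out of this part. It added up to 3 called members of each list with the largest change, or its 2 most expressed members where none was called, the sort markers and other fixed genes (Sdc1, Ptprc, Ly6g, Itgax, Slc2a1, Slc2a3, Prdm1, Irf4, Xbp1, Tnfrsf17, Jchain and immunoglobulin constant genes), and up to 6 interaction genes with the lowest adjusted p. Of the 263 results this gave, the text names a part. Gm10800 and the genes of the second neutrophil list stand outside the rule. Gm10800 and 5 of the 27 genes of that list (Cd177, Pglyrp1, Wfdc21, Anxa1 and Ms4a3) were chosen after their values were seen, and the other 22 before.

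The share of deposited TPM from immunoglobulin loci and the share of each of 8 heavy chain isotypes in heavy chain constant TPM were compared in 7 comparisons by two-sided exact permutation tests of the difference of group means, within strata for averaged comparisons (400 arrangements, smallest p 0.005, or 20 arrangements for 3 against 3, smallest p 0.1), and adjusted over the isotypes. Correlations of effects across genes were set against 1000 simulated data sets without effects. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.

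The labels do not say whether replicates of the same number come from the same mice. Same-number libraries were read as paired in a comparison only where, across tested genes, the deviations from the group mean correlated above 0.1 in each pair. This held for 2NBDG within B220- (0.19, 0.156 and 0.307) and for B220 within 2NBDG+ (0.386, 0.193 and 0.415) and within 2NBDG- (0.214, 0.193 and 0.322), hence for averaged B220. It did not hold for 2NBDG within B220+ (0.297, 0.089 and 0.201), hence not for averaged 2NBDG or the interaction, or for bone marrow (-0.191, -0.069 and -0.029). Across 200 immunoglobulin V genes, spleen libraries of the same number correlated at 0.617 to 0.874, in 2NBDG pairs at 0.819 to 0.874. This was used only as a hint. For bone marrow and B220-2NBDG+ it was -0.178 for numbers 1 and 2 and 0.506 for number 3, so the numbers there do not mark pairs. With 1 and 2 exchanged it was 0.397 and 0.468, which looks like pairs, but tested genes (0.168, 0.079 and -0.029) missed the rule, so the bone marrow block and splits did not use this. The counts with a replicate block were computed in the same run as this check.

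The alternatives set beforehand were TPM as deposited, median-of-ratios scaling, a pseudocount of 0.1, no filter (20795 genes), a replicate block, a fit of the compared groups alone, transcripts in place of genes (24732 tested), constant genes alone, secreted forms alone, an estimated correlation, and leaving out each library in turn. After seeing the data, limma-voom on estimated reads, subtraction of the mean TPM of 1465 olfactory and vomeronasal receptor genes, leave-outs for the correlation of effects and the immunoglobulin share of estimated reads were added. The gene test was tested on simulated data that had 200 genes changed by a factor of 1.5, 2 or 4. It recovered 26.9%, 70.1% and 95.5% of them for averaged 2NBDG, 29.9%, 65.7% and 92.4% for averaged B220, 14.9%, 49.3% and 90.9% for bone marrow, and 0%, 9% and 59.1% for the interaction, with 0.8% to 5.6% of calls false over the 8 comparisons. No library was left out of the main comparisons.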

Results

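RNA was sequenced from mouse plasma cells, the antibody-secreting cells of the B lineage, taken without treatment or immunisation from male C57Bl6/N mice aged 8 to 12 weeks. The cells carried high CD138 and lacked Ly6g and CD11c. They were sorted by B220, a form of CD45 carried by B cells, and by uptake of 2NBDG, a fluorescent analogue of glucose. Spleen gave 4 subsets (B220+2NBDG-, B220-2NBDG-, B220+2NBDG+ and B220-2NBDG+) and bone marrow gave 1 (BMPC, B220- and 2NBDG+), with 3 biological replicates of about 30000 cells in each of these 5 groups. The 15 libraries held 17290257 to 24876424 estimated reads. Of these, 4407070 to 9916079 lay outside the immunoglobulin genes, with the highest group mean in B220+2NBDG- (8925293) and the lowest in B220-2NBDG+ (5500418). Between 9411 and 10663 genes reached 1 TPM once immunoglobulin genes were set aside, and mitochondrially encoded genes took 10.1% to 13.5% of the remaining TPM. Along the first principal component (29.8% of the variance) the libraries ran from B220+2NBDG- (-44.1 to -24.4), through the other spleen groups, to BMPC (41.8 to 51.6). Replicate 3 of B220+2NBDG- stood apart, with Pearson r across genes of 0.939 and 0.946 to its replicates against 0.965 to 0.976 for all other replicate pairs.

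Immunoglobulin transcripts filled most of every library, and filled more of it in the spleen subsets that took up 2NBDG and in those that lacked B220. Immunoglobulin loci held 91.6% ± 0.53 of the deposited TPM in B220+2NBDG-, 94.7% ± 0.15 in B220-2NBDG-, 95.4% ± 0.23 in B220+2NBDG+, 96.4% ± 0.17 in B220-2NBDG+ and 95.5% ± 0.74 in BMPC (SD, n = 3 each). The share was 2.73 percentage points higher in 2NBDG+ than in 2NBDG- spleen cells, in both B220 strata. It was 2.01 points higher in B220- than in B220+ cells, in both 2NBDG strata. Each difference had p = 0.005 by a two-sided exact permutation test, the smallest p that 400 arrangements allow. Within single strata the differences were 3.75 and 1.71 points for 2NBDG and 0.99 and 3.03 for B220. Each had exact permutation p = 0.1, the smallest for 3 against 3. Bone marrow differed from spleen B220-2NBDG+ by -0.86 points (exact permutation p = 0.3). The J segments, whose median effective length in the table is 3.41 nt, took 57.5% to 62.7% of TPM. From the constant genes alone the differences were 0.47 points for 2NBDG (exact permutation p = 0.065) and 0.20 points for B220 (exact permutation p = 0.42). As a share of estimated reads, immunoglobulin genes held 55.2%, 66.3%, 68.8%, 74.2% and 73.0% in the 5 groups in the order above.

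The heavy chain made by the cells shifted away from IgM with 2NBDG uptake. Ighm gave 72.6% ± 6.1 of heavy chain constant TPM in B220+2NBDG- and 79.5% ± 4.6 in B220-2NBDG-, but 55.2% ± 8.5 in B220+2NBDG+ and 57.9% ± 7.7 in B220-2NBDG+ (SD, n = 3 each). The difference was -19.5 percentage points (adjusted p = 0.04, exact permutation). Ighg2b rose by 8.40 points (adjusted p = 0.04, exact permutation), from 10.8% ± 2.9 and 6.09% ± 0.83 to 18.5% ± 5.6 and 15.2% ± 5.3. Ighg2c (3.82 points, adjusted p = 0.05), Ighd (-0.041, 0.05) and Igha (5.50, 0.056) did not pass the exact permutation test without pairs. Nor did Ighg1 (0.72, 0.245), Ighg3 (1.17, 0.245) and Ighe (-0.041, 0.167). Ighd did without B220+2NBDG- replicate 3 (0.04), Igha without B220+2NBDG+ replicate 3 (0.03) and Ighg2c without B220+2NBDG- replicate 1 (0.04) or B220+2NBDG+ replicate 3 (0.0267). All 6 passed with a replicate block (adjusted p = 0.0312 each, exact permutation, the smallest of 64 arrangements). On tested genes 1 of the 6 same-number pairs missed the pairing rule (0.089). Across V genes all 6 correlated at 0.819 to 0.874, which argues for the block. In B220- against B220+ cells, Ighg2c (-3.83 points) and Ighd (-0.046) fell, each at adjusted p = 0.02 by exact permutation. Igha (5.29, adjusted p = 0.107 without pairs), Ighg1 (-0.82, 0.233), Ighg3 (-1.39, 0.233), Ighm (4.82, 0.269) and Ighg2b (-4.01, 0.21) passed neither test. Igha, Ighg1 and Ighg3 kept their sign in each same-number pair. Bone marrow cells carried the most Igha: 44.0% ± 16.6 of heavy chain TPM against 16.1% ± 4.5 in spleen B220-2NBDG+ (p = 0.1, adjusted p = 0.4, exact permutation). The Ighm share there was 42.1% ± 20 against 57.9% ± 7.7. The membrane form of Ighm stayed a small part of its TPM, from 1.46% in B220+2NBDG- to 0.63% in B220-2NBDG+. The Ighm call ended without B220+2NBDG- replicate 2 (adjusted p = 0.0533, exact permutation) or B220-2NBDG- replicate 3 (0.0667). That of Ighg2b ended without B220+2NBDG- replicate 2 or 3 (0.0533 each), B220-2NBDG- replicate 1, 2 or 3 (0.05, 0.0533 and 0.0667) or B220+2NBDG+ replicate 1 or 2 (0.06 each). The unpaired B220 call of Ighd ended on secreted forms alone (0.233) and without B220-2NBDG- replicate 1, 2 or 3 (0.267, 0.229 and 0.193) or B220-2NBDG+ replicate 3 (0.0533). That of Ighg2c ended without B220-2NBDG- replicate 1, 2 or 3 (0.24, 0.229 and 0.12) or B220-2NBDG+ replicate 1, 2 or 3 (0.08, 0.1 and 0.0533).

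**Figure D1:**
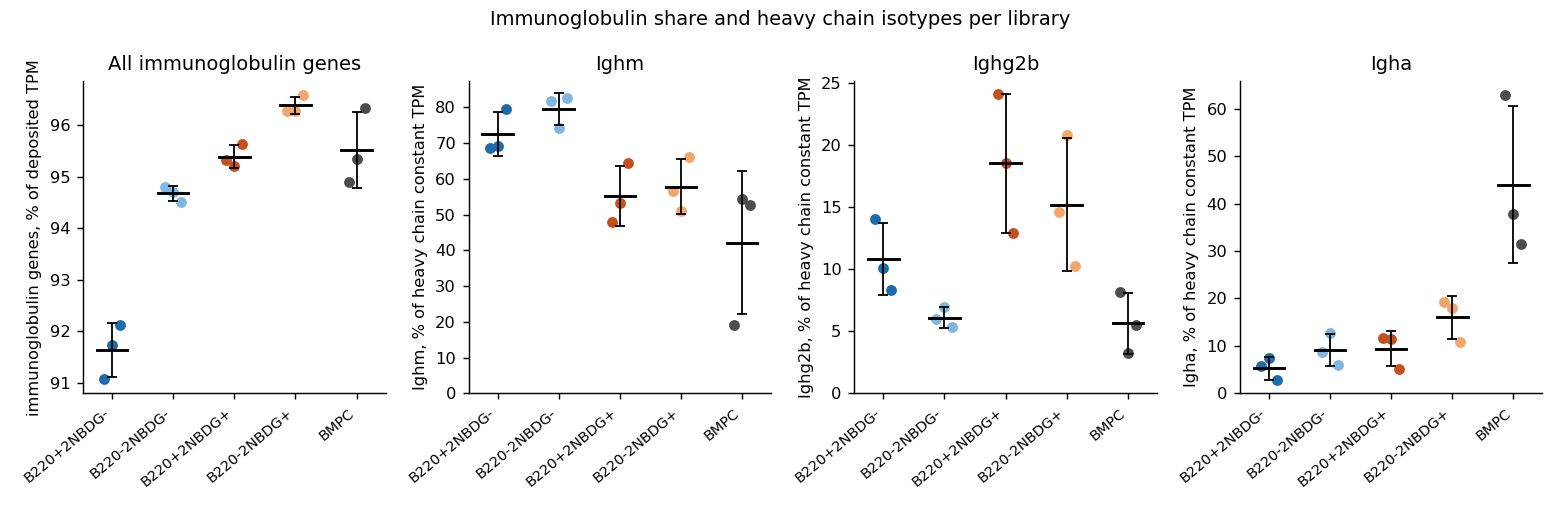
Immunoglobulin share of deposited TPM and the Ighm, Ighg2b and Igha shares of heavy chain constant TPM (y axes, percent) in the 5 groups (x axis), with 1 point per library and bars for the mean and SD. Ighm lies between 68.7% and 82.6% in the 2NBDG- spleen libraries and between 47.9% and 66.1% in the 2NBDG+ spleen libraries, and Igha reaches 62.8% in a bone marrow library.

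The first comparison asks how plasma cells of the spleen that took up 2NBDG differed from those that did not, averaged over B220. Cells with uptake carried more RNA of a monocarboxylate transporter family member and of some plasma cell genes, and much less RNA of cell division genes. Neither the plasma cell nor the cell cycle list call held with an estimated correlation. Slc16a5, the transporter, lies on chromosome 11 (ENSMUSG00000045775.15, 115462474 to 115474398, GRCm38). It stood at 27.7 ± 6.5 and 34.4 ± 2.7 TPM in B220+2NBDG+ and B220-2NBDG+ against 3.60 ± 0.27 and 5.76 ± 1.3 TPM in B220+2NBDG- and B220-2NBDG- (mean ± SD, n = 3 each). Its log2 fold change was 2.51 ± 0.14 (SE, adjusted p = 8.73e-07). Cldn7, a tight junction claudin (ENSMUSG00000018569.12, chromosome 11, 69964779 to 69967885), rose by 1.92 ± 0.29 (adjusted p = 0.00178). The next largest rises were in Pdzk1ip1 (1.53 ± 0.20), Spag6 (1.49 ± 0.20), the metallothionein Mt2 (1.37 ± 0.26), Tmem205 (1.32 ± 0.15), Cpq (1.28 ± 0.24) and Slc7a4 (1.27 ± 0.18). The largest fall was in Esco2, which acts in sister chromatid cohesion (-2.40 ± 0.31, adjusted p = 6.54e-04; ENSMUSG00000022034.10, chromosome 14, 65819038 to 65833994). It was followed by Cdkn3 (-1.99 ± 0.21), the cyclin Ccnb2 (-1.95 ± 0.19), Knl1 (-1.91 ± 0.24), Pclaf (-1.84 ± 0.26), Birc5 (-1.82 ± 0.25) and Cdca3 (-1.80 ± 0.16). The mitotic kinase Cdk1 fell alike (-1.80 ± 0.21, adjusted p = 3.89e-04; ENSMUSG00000019942.13, chromosome 10, 69335146 to 69352938). Cdk1 averaged 105 ± 9.8, 32.8 ± 12, 37.7 ± 14 and 6.85 ± 2.7 TPM in B220+2NBDG-, B220-2NBDG-, B220+2NBDG+ and B220-2NBDG+. Of 11246 genes tested with limma, 726 were called at an adjusted p under 0.05, 227 higher and 499 lower, in 426 of them with libraries that did not overlap in either stratum. Over all genes this held for 622, or 5.5% (chance gives 0.5%). On TPM as deposited 28 were higher and 8258 lower, and Mt2 lost its call (adjusted p = 0.0656). There the growing immunoglobulin share lowers other genes, and the pseudocount of 1 shrinks log2 fold changes of low values. The median of all tested genes moves from -0.04 to -0.21. Genes with a called transcript numbered 370. The count was 470, 466 or 1163 without B220+2NBDG- replicate 1, 2 or 3, 477 or 475 without B220-2NBDG- replicate 2 or 3, 461 without B220+2NBDG+ replicate 3, and 459 or 458 without B220-2NBDG+ replicate 1 or 3.

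Among the gene lists, the cell cycle list had the largest median in 2NBDG+ cells on the main scale, though not on TPM as deposited (-0.71, against -1.02 for MHC class II and -0.82 for ribosomal proteins). All 36 called members of 44 fell (41 adjusted over the list alone), with a median log2 fold change of -1.20 (preset adjusted p = 6.98e-37, 0.0733 with an estimated correlation). Plasma cell identity genes went the other way, with 5 of 29 higher (6 adjusted over the list alone) and a median of 0.09, though of -0.39 on TPM as deposited. Their preset adjusted p was 0.0006 (adjusted p = 0.414 with an estimated correlation, and 0.198 on TPM as deposited). Its member Prg2, best known as the eosinophil granule major basic protein (1.19 ± 0.09, adjusted p = 1.45e-05; ENSMUSG00000027073.5, chromosome 2, 84980461 to 84983632), rose. So did Tnfrsf17, the plasma cell survival receptor BCMA (0.72 ± 0.10, adjusted p = 9.01e-04), and Jchain (0.74 ± 0.11, adjusted p = 0.00128). Amino acid transport and ATF4 target genes rose, 2 of 25 (4 adjusted over the list alone), with a median of 0.20, or -0.13 on TPM as deposited. Their preset adjusted p was 8.81e-06 (adjusted p = 0.414 with an estimated correlation), and Asns, asparagine synthetase, stood at 0.83 ± 0.11. Autophagy and lysosome genes rose, 8 of 35 (12 adjusted over the list alone), with a median of 0.22, or -0.21 on TPM as deposited. Their preset adjusted p was 1.3e-06 (adjusted p = 0.0837 with an estimated correlation, and 0.263 on TPM as deposited), and the protease Ctsl stood at 0.90 ± 0.14. Monocyte, macrophage and dendritic cell markers had a median of 0.94 here, with 1 of 22 called higher and the list call lost with an estimated correlation. Which cells this RNA came from was not settled. None of Tnfrsf17 (0.013, adjusted p = 0.926), Jchain (0.035, 0.809), Asns (0.12, 0.32) and Ctsl (0.16, 0.216) was called on TPM as deposited, where the first 2 lay near 0.

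Some B cell and lipid synthesis genes lay lower with 2NBDG uptake, 1 of 33 and 3 of 21 called, and neither list call held with an estimated correlation. MHC class II genes fell, 3 of 11 (6 adjusted over the list alone), with a median of -0.59 (preset adjusted p = 2.26e-04, 0.414 with an estimated correlation). Cholesterol biosynthesis genes fell too, 3 of 21 (7 adjusted over the list alone), with a median of -0.33 (preset adjusted p = 0.0006, 0.306 with an estimated correlation). Among them were Pmvk (-0.57 ± 0.13) and Cyp51, lanosterol demethylase (-0.53 ± 0.10, adjusted p = 0.00716). Ribosomal protein genes fell slightly, 3 of 41 (8 adjusted over the list alone), with a median of -0.13. Their preset adjusted p was 1.31e-04 (adjusted p = 0.603 with an estimated correlation, and 0.0898 without B220+2NBDG- replicate 3). B cell identity genes had a median of -0.34 and 1 of 33 called lower, also when adjusted over the list alone (preset adjusted p = 0.0207, 0.76 with an estimated correlation). MYC target genes had a median of -0.16 and 1 of 28 called lower by both counts (preset adjusted p = 0.0384, 0.469 with an estimated correlation). The B cell call ended without B220+2NBDG- replicate 1 (0.0575) or 2 (0.198), B220-2NBDG- replicate 2 (0.0713), B220+2NBDG+ replicate 3 (0.0925) or B220-2NBDG+ replicate 3 (0.0738), and on TPM as deposited (0.21). The MYC call ended without B220+2NBDG- replicate 2 (0.0692) or 3 (0.0783), B220-2NBDG- replicate 3 (0.15), B220+2NBDG+ replicate 1 (0.0972) or B220-2NBDG+ replicate 1 (0.0527) or 2 (0.0597), and with median-of-ratios scaling (0.0834). Blk, a B cell Src-family kinase, fell by 0.78 on the log2 scale (SE 0.15, adjusted p = 0.00677). Mitochondrially encoded genes (0 of 13 called by either count) had a median of 0.28, or -0.42 on TPM as deposited (preset adjusted p = 9.51e-05, 0.424 with an estimated correlation). Fatty acid oxidation genes (1 of 20 higher by both counts) had a median of 0.12, or -0.33 on TPM as deposited (preset adjusted p = 0.0128, 0.438 with an estimated correlation). Oxidative stress genes (1 of 23 higher, 3 adjusted over the list alone) had a median of 0.10, or -0.42 on TPM as deposited (preset adjusted p = 0.0138, 0.306 with an estimated correlation). Fatty acid oxidation lost its call without B220+2NBDG- replicate 3 (adjusted p = 0.0697), and oxidative stress defence without B220+2NBDG+ replicate 3 (0.0584) or B220-2NBDG+ replicate 3 (0.0647). None of these 3 lists was called on TPM as deposited (0.737, 0.538 and 0.523).

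Genes of glucose use showed no shared change with 2NBDG uptake. Of 25 glucose transport and glycolysis genes, 2 fell and none rose (4 and 1 adjusted over the list alone; median -0.08, adjusted p = 0.465). These were Ldha (-0.35 ± 0.09, adjusted p = 0.0374) and Pgk1 (-0.30 ± 0.07, adjusted p = 0.0283). Each call ended in 9 of the 12 fits that left out 1 library, at adjusted p up to 0.101 and 0.075. For Ldha the 3 libraries whose removal kept the call were B220+2NBDG- 3, B220+2NBDG+ 2 and B220-2NBDG+ 2, and for Pgk1 they were B220+2NBDG- 3, B220-2NBDG- 1 and B220+2NBDG+ 3. The glucose transporters Slc2a1 (12.0, 18.0, 14.3 and 16.3 TPM in B220+2NBDG-, B220-2NBDG-, B220+2NBDG+ and B220-2NBDG+; 0.04 ± 0.16, adjusted p = 0.929) and Slc2a3 (-0.02 ± 0.35, adjusted p = 0.988) did not pass the test. The TCA cycle (adjusted p = 0.997), nuclear-encoded oxidative phosphorylation (0.946), N-glycosylation (0.928), unfolded protein response (0.78) and secretory transport lists (0.961) were not called either. On TPM as deposited those for the TCA cycle (adjusted p = 0.0338), oxidative phosphorylation (7.45e-05), N-glycosylation (0.0179) and secretory transport (2.02e-05) were called lower. Without B220+2NBDG- replicate 3 that for the unfolded protein response was called (0.0482). Single members of these fell, among them B4galt1, a galactosyltransferase (-0.77 ± 0.17, adjusted p = 0.0166), Ssr2, a translocon subunit (-0.53 ± 0.08, adjusted p = 0.0013), and the chaperone Calr (-0.36 ± 0.08, adjusted p = 0.0149). In 8 of the 31 lists, none of them called, median, mean and test differed in sign. Prdm1 (0.06 ± 0.23), Irf4 (-0.06 ± 0.20) and Xbp1 (0.20 ± 0.15), the transcription factors of plasma cells, were not called. Nor were the sort markers Sdc1 (CD138, 0.49 ± 0.29), Ptprc (the CD45 gene, -0.32 ± 0.21), Ly6g (-0.65 ± 0.27) and Itgax (CD11c, 0.05 ± 0.17).

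RNA of other cell types also moved with 2NBDG. T cell markers fell, 5 of 16 (13 adjusted over the list alone), with a median of -1.09. Their preset adjusted p was 1.3e-06 (adjusted p = 0.306 with an estimated correlation, and 0.737 on TPM as deposited). Trac, the T cell receptor alpha constant gene, fell by -2.37 ± 0.52 (adjusted p = 0.0162; ENSMUSG00000076928.5, chromosome 14, 54220521 to 54224206). It averaged 82.0 ± 72 TPM in B220+2NBDG-, where the libraries held 158, 74.6 and 13.5 TPM. It averaged 27.1 ± 12, 10 ± 4.3 and 4.28 ± 0.75 TPM in B220-2NBDG-, B220+2NBDG+ and B220-2NBDG+. Monocyte, macrophage and dendritic cell markers had a median of 0.94, with 1 of 22 called higher (2 adjusted over the list alone; preset adjusted p = 1.58e-05, 0.414 with an estimated correlation). Erythroid markers had a median of 0.53, with 0 of 13 called by either count (preset adjusted p = 0.0364, 0.76 with an estimated correlation). Mast cell, basophil and eosinophil markers had a median of 0.84, with 1 of 5 called higher (2 adjusted over the list alone; preset adjusted p = 0.0364, 0.332 with an estimated correlation). The erythroid call ended without B220+2NBDG- replicate 1 (adjusted p = 0.0935) or 2 (0.12), B220-2NBDG- replicate 1 (0.115) or 2 (0.232), B220+2NBDG+ replicate 3 (0.575) or B220-2NBDG+ replicate 3 (0.536). The mast cell call ended without B220+2NBDG- replicate 1 (0.0585), B220-2NBDG- replicate 1 (0.069) or 2 (0.0672), B220+2NBDG+ replicate 3 (0.0815) or B220-2NBDG+ replicate 3 (0.092). Markers of NK cells (adjusted p = 0.288), neutrophils (0.997), megakaryocytes (0.288) and stroma (0.928) were not called. Neutrophil (2.83e-06) and megakaryocyte markers (0.00523) were called on TPM as deposited, where their medians (-0.11 and -0.03) lay less far below 0 than that of all genes (-0.21). Reads on 1465 olfactory and vomeronasal receptor genes, silent in plasma cells, made up 5719 ± 554 per 1000000 non-immunoglobulin reads in B220-2NBDG- against 2215 ± 560, 1771 ± 198 and 2082 ± 657 in B220+2NBDG-, B220+2NBDG+ and B220-2NBDG+ (SD, n = 3 each).

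**Figure D2:**
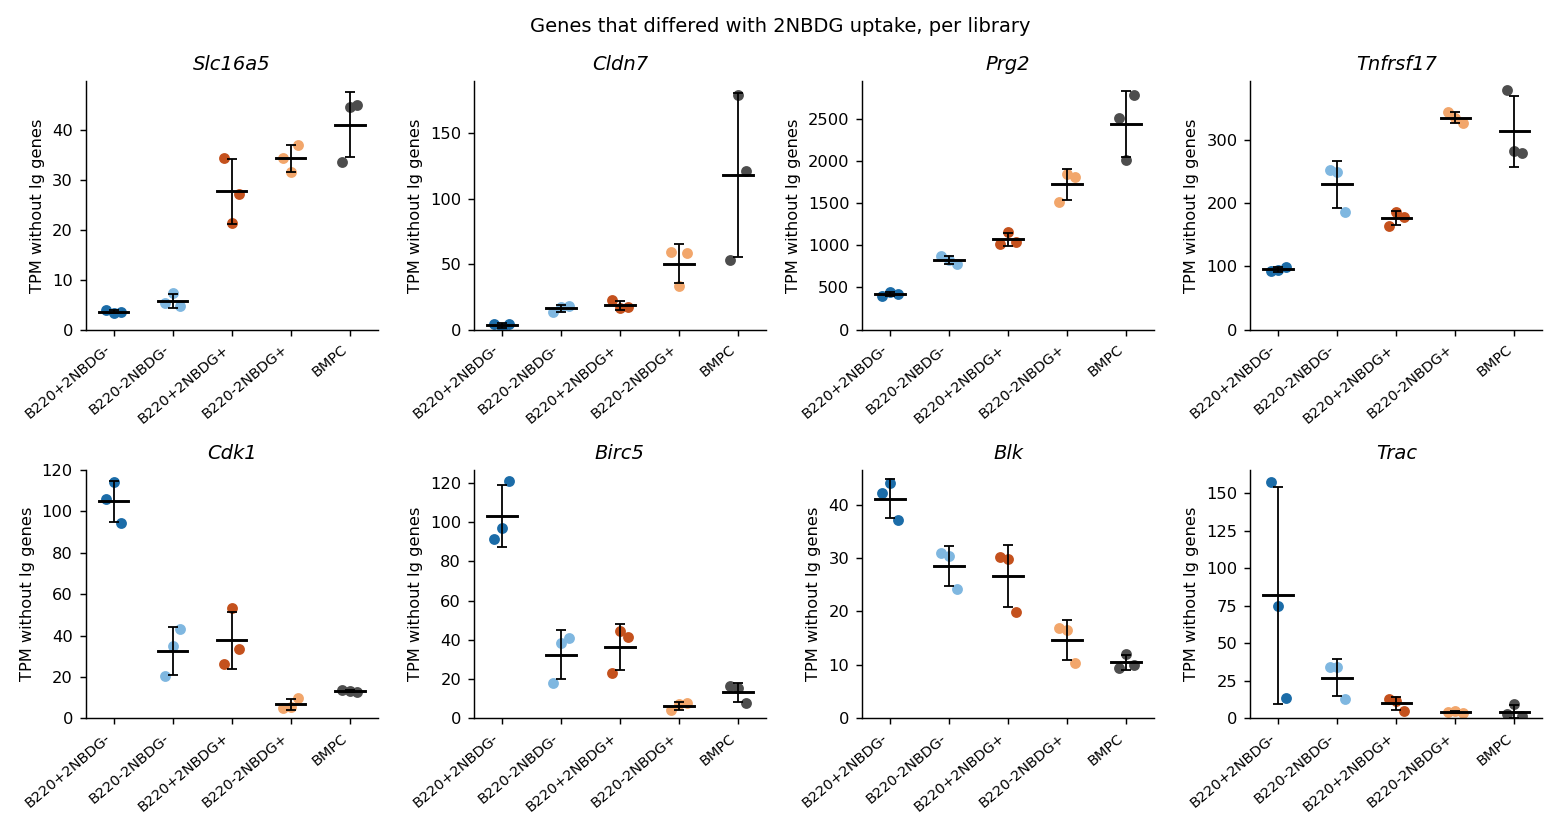
TPM without immunoglobulin genes (y axes, from 0) of 8 genes in the 5 groups (x axis), with 1 point per library and bars for the mean and SD. Slc16a5 is at most 5.76 TPM on average in 2NBDG- spleen groups and at least 27.7 TPM in 2NBDG+ groups, Cdk1 and Birc5 step down from B220+2NBDG- to B220-2NBDG+, and Trac varies widely among the B220+2NBDG- libraries.

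Within single B220 strata, the change in Slc16a5 was 2.62 ± 0.20 in B220+ cells and 2.40 ± 0.20 in B220- cells (log2 ± SE, 3 against 3 libraries, adjusted p = 4.21e-05 and 6.19e-05). Prg2 rose in both strata, by 1.33 ± 0.12 and 1.06 ± 0.12, and Cdk1 fell in both, by -1.51 ± 0.30 and -2.09 ± 0.30. Tnfrsf17 rose by 0.88 ± 0.14 in B220+ cells (adjusted p = 0.011), while its change in B220- cells was 0.56 ± 0.14 (adjusted p = 0.0505). In B220+ cells 247 genes were called, 117 higher and 130 lower, and on TPM as deposited 77 and 7350. That count was 5 with only the compared groups in the fit, 141 without a filter, 485 with the replicate block, 423 with voom and 35 by transcripts. In B220- cells, where same-number replicates resembled each other enough to be read as pairs, 314 were called, 21 higher and 293 lower, and on TPM as deposited 6 and 2626. That count was 159 with only the compared groups, 764 without a filter and 119 by transcripts. The B220+ count was 49, 42 or 376 without B220+2NBDG- replicate 1, 2 or 3 and 79 or 29 without B220+2NBDG+ replicate 1 or 3. The B220- count was 177 or 125 without B220-2NBDG- replicate 2 or 3 and 150 or 148 without B220-2NBDG+ replicate 1 or 3.

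The second comparison asks how B220- plasma cells of the spleen differed from B220+ ones, averaged over 2NBDG. Cells without B220 carried more RNA of some plasma cell and amino acid genes and less of cell division, antigen presentation and B cell genes. None of these 5 list calls held with an estimated correlation, and the first 2 medians were negative on TPM as deposited. Reg2 (1.74 ± 0.24, SE, adjusted p = 6.16e-04; ENSMUSG00000023140.4, chromosome 6, 78395623 to 78408106), of the Reg family of secreted lectin-like proteins, rose. It averaged 58.8 ± 22 and 12.5 ± 6.6 TPM in B220-2NBDG- and B220-2NBDG+ against 7.45 ± 1.8 and 6.65 ± 0.34 TPM in their B220+ counterparts (mean ± SD, n = 3 each). Next came Cldn7 (1.73 ± 0.29) and Cox6a2, a subunit of cytochrome c oxidase (1.67 ± 0.21, adjusted p = 3.02e-04; ENSMUSG00000030785.8, chromosome 7, 128205435 to 128206387). Then came Mt2 (1.63 ± 0.26), Rab3b (1.46 ± 0.21), Spns3 (1.43 ± 0.17), Fut1 (1.41 ± 0.17) and Pcbd1 (1.35 ± 0.19). The largest falls were again in cell division genes: Esco2 (-2.30 ± 0.31, adjusted p = 5.02e-04), Pclaf (-2.12 ± 0.26), Cdkn3 (-2.05 ± 0.21), Rrm2 (-2.01 ± 0.21), Birc5 (-2.01 ± 0.25) and Cdk1 (-2.00 ± 0.21). Rrm2, a ribonucleotide reductase subunit (adjusted p = 1.12e-04; ENSMUSG00000020649.11, chromosome 12, 24708241 to 24714146), stood at 499 ± 119, 156 ± 54, 190 ± 56 and 37.2 ± 10 TPM in B220+2NBDG-, B220-2NBDG-, B220+2NBDG+ and B220-2NBDG+. In all, 973 genes were called, 315 higher and 658 lower, in 616 of them with libraries that did not overlap in either stratum. Over all genes this held for 854, or 7.6% (chance gives 0.5%). Genes with a called transcript numbered 572. On TPM as deposited 167 were higher and 6694 lower (median of all tested genes -0.17 against -0.09). With median-of-ratios scaling, which centres that median, 552 were higher and 461 lower. The count was 592 without B220+2NBDG+ replicate 2 and 569 without B220-2NBDG- replicate 1.

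The cell cycle list fell with loss of B220 as with 2NBDG uptake, with 38 of 44 members called (40 adjusted over the list alone). Its median was -1.35, or -0.72 on TPM as deposited (preset adjusted p = 1.9e-35, 0.0834 with an estimated correlation). MHC class II genes fell in 9 of 11 cases (11 adjusted over the list alone), with a median of -1.39 (preset adjusted p = 4.2e-11, 0.227 with an estimated correlation). They were led by H2-Oa (-1.76 ± 0.34), H2-Aa (-1.73 ± 0.21, adjusted p = 2.7e-04; ENSMUSG00000036594.15, chromosome 17, 34282744 to 34287823) and H2-DMb2 (-1.55 ± 0.36). H2-Aa averaged 2532 ± 719, 741 ± 210, 1425 ± 463 and 436 ± 133 TPM in B220+2NBDG-, B220-2NBDG-, B220+2NBDG+ and B220-2NBDG+. B cell identity genes fell, 9 of 33 (22 adjusted over the list alone), with a median of -0.63 (preset adjusted p = 2.71e-07, 0.543 with an estimated correlation). Among them were Cr2, complement receptor 2 (-2.00 ± 0.51, adjusted p = 0.0289), and the inhibitory receptor Cd72 (-1.87 ± 0.43, adjusted p = 0.0167; ENSMUSG00000028459.11, chromosome 4, 43446462 to 43454628). The Cr2 call ended with a pseudocount of 0.1, without a filter, and without B220+2NBDG- replicate 2, B220-2NBDG- replicate 1, B220+2NBDG+ replicate 2 or 3, or B220-2NBDG+ replicate 1 or 3, at adjusted p from 0.0508 to 0.0811. Cholesterol biosynthesis genes fell, 5 of 21 (9 adjusted over the list alone), with a median of -0.38 (preset adjusted p = 4.34e-04, 0.355 with an estimated correlation). MYC target genes fell, 4 of 28 (6 adjusted over the list alone), with a median of -0.26 (preset adjusted p = 0.00175, 0.404 with an estimated correlation). Ptprc, which encodes all forms of CD45 and so does not measure B220 itself, had a log2 fold change of -0.34 ± 0.21 (adjusted p = 0.355).

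Plasma cell identity genes rose with loss of B220, 6 of 29 (7 up and 1 down adjusted over the list alone). Their median was 0.19, or -0.23 on TPM as deposited (preset adjusted p = 1.13e-04, 0.464 with an estimated correlation). Ly6k (1.21 ± 0.25, adjusted p = 0.0098), Tnfrsf17 (1.09 ± 0.10, adjusted p = 9.54e-05; ENSMUSG00000022496.5, chromosome 16, 11313812 to 11320074) and Jchain (0.85 ± 0.11, adjusted p = 3.37e-04) rose. Amino acid transport and ATF4 target genes rose, 7 of 25 (11 up and 2 down adjusted over the list alone). Their median was 0.26, or -0.05 on TPM as deposited (preset adjusted p = 1.58e-08, 0.355 with an estimated correlation). Asns stood at 0.94 ± 0.11 (adjusted p = 2.5e-04; ENSMUSG00000029752.12, chromosome 6, 7675169 to 7693254). Mitochondrially encoded genes (0 of 13 called by either count) had a median of 0.17, or -0.33 on TPM as deposited (preset adjusted p = 0.045, 0.933 with an estimated correlation). Neutrophil markers (1 of 18 called higher, 0 adjusted over the list alone) had a median of 0.35, or -0.02 on TPM as deposited (preset adjusted p = 0.00604, 0.825 with an estimated correlation). The first of these calls ended without B220+2NBDG- replicate 1 (adjusted p = 0.0955) or 2 (0.314), B220-2NBDG- replicate 1 (0.0851) or 3 (0.22), B220+2NBDG+ replicate 1 (0.0733) or 2 (0.277) or B220-2NBDG+ replicate 3 (0.117). The second ended without B220-2NBDG- replicate 3 (0.0753), B220+2NBDG+ replicate 1 (0.161) or B220-2NBDG+ replicate 3 (0.12). Autophagy and lysosome genes were not called (3 of 35 up and 1 down; adjusted p = 0.0708), but were with the replicate block (adjusted p = 0.0499) and without B220+2NBDG+ replicate 3 (0.026) or B220-2NBDG+ replicate 2 (0.0312). Wipi1 of that list rose by 1.17 ± 0.18 (adjusted p = 0.00115).

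Genes of glucose use and of the secretory pathway were not called as lists with loss of B220 on the main scale, although single members fell. The TCA cycle (adjusted p = 0.0323), oxidative phosphorylation (0.00267), N-glycosylation (0.0318) and secretory transport (2.56e-04) were called lower on TPM as deposited, and without a filter glycolysis (0.0382), the TCA cycle (0.0205) and secretory transport (0.0382). Of the glycolysis genes 1 of 25 rose and 4 fell (2 and 6 adjusted over the list alone; median -0.17, adjusted p = 0.67), with enolase Eno1 at -0.74 ± 0.15 (adjusted p = 0.00789). The chaperone Hsp90b1 (-0.49 ± 0.08, adjusted p = 0.00312) averaged 3281 ± 152 and 2650 ± 437 TPM in B220+2NBDG- and B220+2NBDG+ against 2345 ± 161 and 1876 ± 125 TPM in B220-2NBDG- and B220-2NBDG+ (SD, n = 3 each). Ssr2 fell by -0.50 ± 0.08 (adjusted p = 0.00129). The unfolded protein response (adjusted p = 0.966), secretory transport (0.762), N-glycosylation (0.929), TCA cycle (0.607), oxidative phosphorylation (0.884), fatty acid oxidation (0.257) and ribosomal protein (0.0808) lists were not called. The ribosomal list was called lower without B220+2NBDG- replicate 1 (0.0394) or 2 (0.00198), B220-2NBDG- replicate 1 (0.05) or 3 (0.0167), B220+2NBDG+ replicate 1 (0.00399) or B220-2NBDG+ replicate 3 (0.0109). Of markers of other cells, T cells (adjusted p = 0.386, with Cd2 at -1.60 ± 0.21), NK cells (0.754), monocytes, macrophages and dendritic cells (0.615), erythroid cells (0.67), megakaryocytes (0.968), mast cells, basophils and eosinophils (0.498) and stroma (0.257) were not called. The T cell list was called without B220+2NBDG- replicate 3 (adjusted p = 0.0204). In 7 of the 31 lists, none called, median, mean and test differed in sign.

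**Figure D3:**
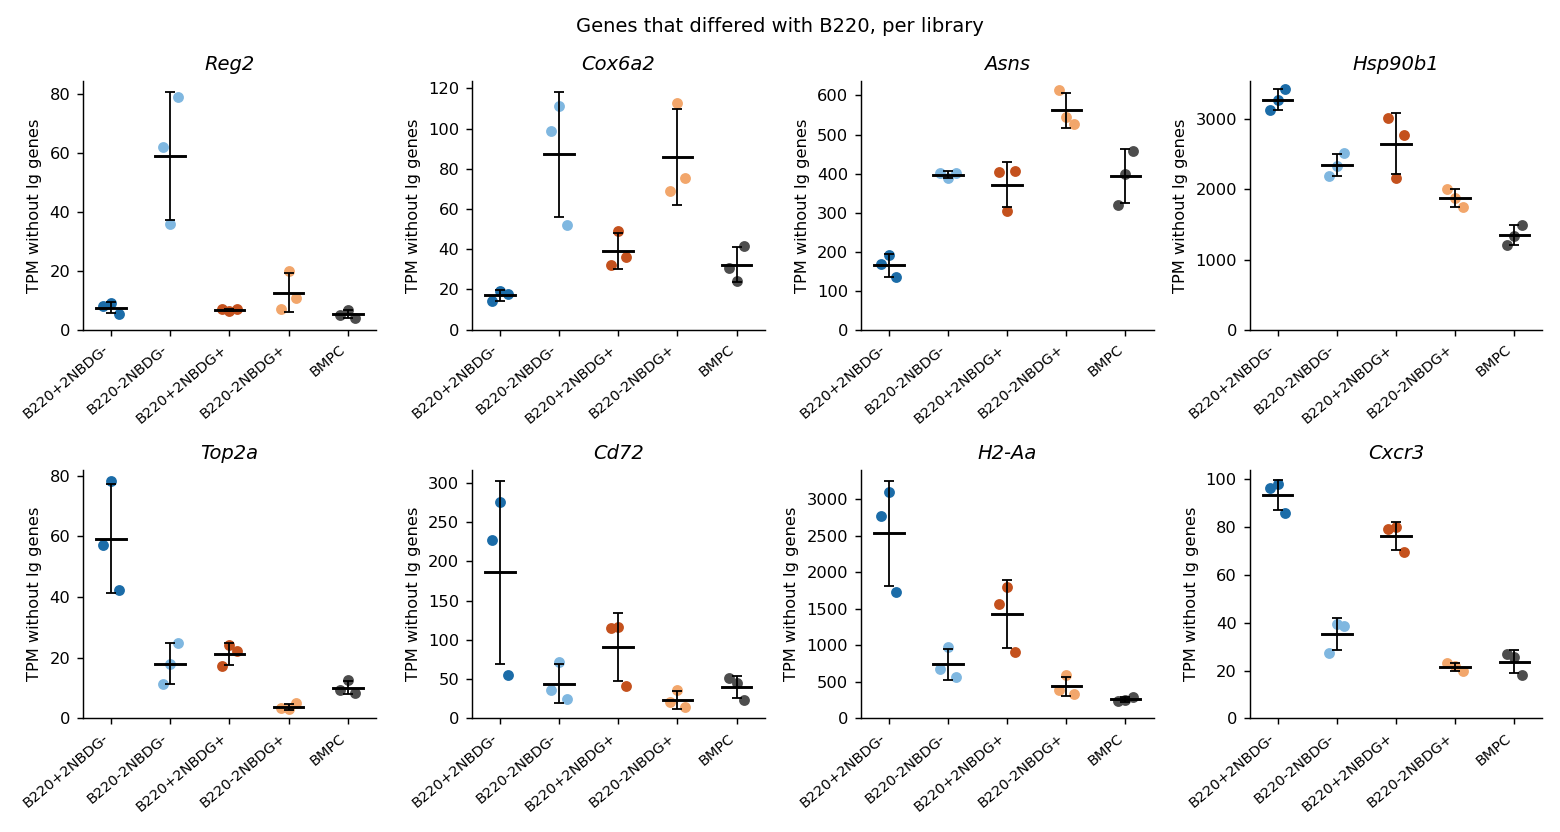
TPM without immunoglobulin genes (y axes, from 0) of 8 genes in the 5 groups (x axis), with 1 point per library and bars for the mean and SD. Cxcr3 averages 93.5 and 76.3 TPM in the B220+ groups and 35.1 and 21.6 TPM in the B220- spleen groups, and Reg2 is highest in B220-2NBDG- at 58.8 TPM.

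Within single 2NBDG strata, Cdk1 fell with loss of B220 by -2.30 ± 0.30 in 2NBDG+ cells and by -1.71 ± 0.30 in 2NBDG- cells (log2 ± SE, 3 against 3 libraries, adjusted p = 0.0021 and 0.00526). H2-Aa fell by -1.69 ± 0.30 and -1.76 ± 0.30. Tnfrsf17 rose by 0.93 ± 0.14 and 1.25 ± 0.14. Reg2 rose by 2.78 ± 0.34 in 2NBDG- cells (adjusted p = 0.00113), while its change in 2NBDG+ cells was 0.71 ± 0.34 (adjusted p = 0.449). In 2NBDG+ cells 151 genes were called, 11 higher and 140 lower, 228 with the replicate block, 38 with only the compared groups, 77 by transcripts, and with median-of-ratios scaling 22 higher and 85 lower. In 2NBDG- cells 589 were called, 306 higher and 283 lower, against 243 higher and 6172 lower on TPM as deposited and 392 higher and 230 lower with median-of-ratios scaling. With the silent-gene background subtracted 278 were higher and 533 lower, and without a filter 742 and 304. The count was 118 with only the compared groups, 992 with voom and 297 by transcripts. The first count was 56 or 95 without B220+2NBDG+ replicate 2 or 3 and 83, 99 or 93 without B220-2NBDG+ replicate 1, 2 or 3. The second was 386 or 377 without B220+2NBDG- replicate 1 or 2 and 229 or 380 without B220-2NBDG- replicate 1 or 3.

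**Figure D4:**
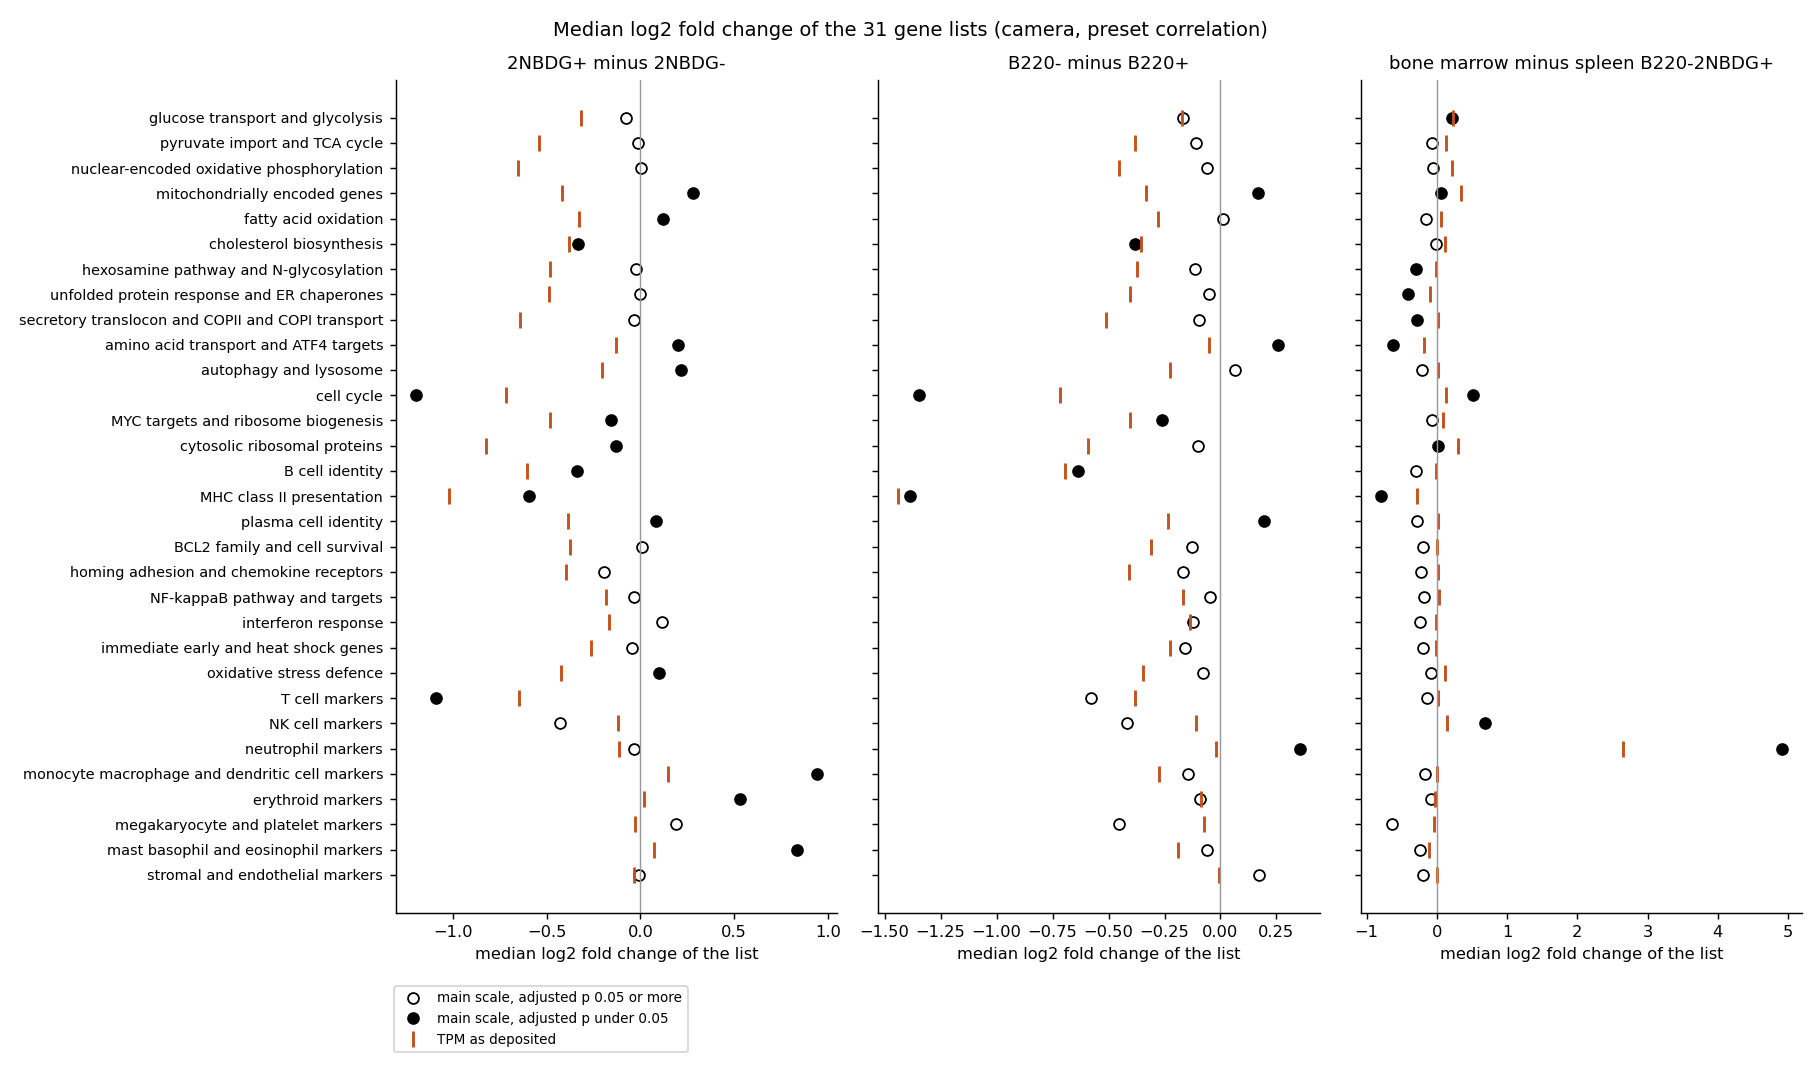
Median log2 fold change (x axis) of the 31 gene lists (y axis) in 3 comparisons, with filled points for an adjusted p under 0.05 at the preset correlation, open points for the others and orange ticks for TPM as deposited. Cell cycle genes lie at -1.20 and -1.35 in the spleen comparisons and at 0.51 in bone marrow against spleen, where neutrophil markers lie at 4.92, and several lists with small positive medians, such as plasma cell identity, have negative ones on TPM as deposited.

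Changes with 2NBDG were correlated across the B220 strata, and changes with loss of B220 across the 2NBDG strata. The 2NBDG effects within B220+ and within B220- correlated across 11246 genes with Pearson r = 0.463 and Spearman rho = 0.422. The B220 effects within 2NBDG+ and within 2NBDG- correlated with r = 0.457 and rho = 0.421 (genes are not independent replicates). Simulated effects-free data that kept the spread between libraries gave mean r values of 0.0053 and 0.0083, with 95% of draws between -0.386 and 0.362 and between -0.307 and 0.32. Genes called lower in both B220 strata with 2NBDG uptake numbered 71, against 3.39 for independent lists, those called higher in both 16, against 0.22, and none went opposite ways. For B220 these counts were 104 against 3.52, 9 against 0.3, and again none opposite. The averaged 2NBDG and B220 effects, which use the same 12 libraries, had r = 0.384 and rho = 0.442. This r lies within the simulated range of -0.742 to 0.874, so a shared change was not shown. Their calls shared 95 higher genes (6.36 for independent lists), 267 lower (29.2) and 85 opposite. Counts for independent lists leave out the shared libraries and the likeness of same-number libraries.

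The test of whether the 2NBDG effect differed between B220- and B220+ cells called 3 genes of 11246, all with a lower effect in B220- cells, and 623 genes had an unadjusted p under 0.05. They were Trav6n-6, a T cell receptor V segment (ENSMUSG00000076802.3, chromosome 14, 53132679 to 53133137), Mapt, the microtubule-binding protein tau (ENSMUSG00000018411.17, chromosome 11, 104231390 to 104332090), and Gm3183 (ENSMUSG00000095954.4, chromosome 5, 94865436 to 94885388). Each was higher in the B220-2NBDG- libraries. Trav6n-6 averaged 3.11 ± 0.81 TPM there and was listed at 0 in the other groups. Mapt averaged 3.06 ± 1.2 TPM against 0.028, 0.023 and 0.089 in the other spleen groups, and Gm3183 1.67 TPM against at most 0.45 TPM. A set of 12 satellite-like Gm genes, among them Gm10800 on chromosome 2 (98666547 to 98667301), reached 32257 ± 8301 TPM in the same libraries against 3201 ± 1915, 1631 ± 231 and 5541 ± 1939 TPM in B220+2NBDG-, B220+2NBDG+ and B220-2NBDG+. The count was 71 higher and 9 lower on TPM as deposited, 26 without a filter, and 0 with a pseudocount of 0.1, with background subtracted, with voom and by transcripts. It was 1 without B220+2NBDG- replicate 1 or 2, B220+2NBDG+ replicate 1 or 3, or B220-2NBDG+ replicate 2 or 3.

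The third comparison sets plasma cells of the bone marrow against spleen cells of the same sort phenotype, B220- and 2NBDG+. Neutrophil genes rose by far the most, some cell division genes rose, and some genes of amino acid supply and of the unfolded protein response fell. With an estimated correlation the neutrophil list call held (adjusted p = 0.00947) and the other 3 did not. Ltf, lactoferrin (ENSMUSG00000032496.7, chromosome 9, 111019271 to 111042767), went from 19.1 ± 10 to 2750 ± 760 TPM (mean ± SD, n = 3 each). Its log2 fold change was 7.22 ± 1.14 (SE, adjusted p = 0.00449). Chil3 (8.03 ± 1.57), Ngp (6.69 ± 0.91), Camp (6.64 ± 0.77, adjusted p = 4.7e-04), S100a8 (5.50 ± 1.26), the ficolin Fcnb (5.47 ± 0.38, adjusted p = 1.88e-05), Lcn2 (5.44 ± 0.80) and the elastase Elane (5.11 ± 0.66) completed the 8 largest rises, all neutrophil markers. Neutrophil markers rose in 14 of 18 cases (18 adjusted over the list alone), with a median of 4.92, or 2.64 on TPM as deposited (preset adjusted p = 1.33e-45). This was the only list of any comparison to hold with an estimated correlation. Ly6g, the neutrophil surface marker gated against in the sort, stood at 10.1 ± 5.2 TPM against 0.739 ± 0.56 TPM (2.59 ± 0.39, adjusted p = 0.00317). Rcn3, an ER calcium-binding protein, fell (-1.69 ± 0.24, adjusted p = 0.00185; ENSMUSG00000019539.11, chromosome 7, 45082913 to 45092221). The ectoenzyme Cd38 went from 35.6 ± 0.50 to 12.5 ± 1.6 TPM (-1.45 ± 0.17, adjusted p = 4.29e-04; ENSMUSG00000029084.5, chromosome 5, 43868553 to 43912375). The other large falls were in Adamdec1 (-3.32 ± 0.71), Rgs1 (-1.87 ± 0.40), Dgkg (-1.51 ± 0.32), Josd2 (-1.45 ± 0.33), Frmpd2 (-1.45 ± 0.29) and Cox6a2 (-1.38 ± 0.29). In all, 216 genes were called, 116 higher and 100 lower, none with overlapping libraries. Over all 11246 genes the libraries did not overlap in 2664, or 23.7% (chance gives 10%). The counts were 98 and 2 on TPM as deposited and 183 and 34 with median-of-ratios scaling (median of all tested genes -0.18, 0.01 on TPM as deposited). The count was 53 with only the compared groups, 138 with voom and 98 by transcripts.

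Chil3 lost its call without B220-2NBDG+ replicate 1 or 2 or BMPC replicate 1 or 2 (adjusted p from 0.0594 to 0.0909), and S100a8 without any of these or BMPC replicate 3 (0.0782 to 0.171). Adamdec1, Rgs1, Dgkg, Josd2, Frmpd2 and Cox6a2 each lost theirs without B220-2NBDG+ replicate 2 or 3 or BMPC replicate 1 or 2, Rgs1 also without BMPC replicate 3, and Dgkg, Josd2, Frmpd2 and Cox6a2 also without B220-2NBDG+ replicate 1 (0.0585 to 0.14 over the 6 genes). Cd38 lost its call on TPM as deposited (adjusted p = 0.072), and Elane (0.0507) and Ly6g (0.0804) in a fit of the 2 groups alone. The count of called genes was 88, 99 or 134 without B220-2NBDG+ replicate 1, 2 or 3 and 133 or 105 without BMPC replicate 1 or 2.

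Cell cycle genes rose in the bone marrow libraries, 5 of 44 (21 up and 1 down adjusted over the list alone). Their median was 0.51, or 0.13 on TPM as deposited (preset adjusted p = 9.15e-23, 0.108 with an estimated correlation). Neutrophil and precursor genes rose in the same libraries (list median 4.92, Elane 5.11), so the cells this RNA and that of other lists came from were not settled. Stmn1 (ENSMUSG00000028832.11, chromosome 4, 134468320 to 134473843) went from 19.8 ± 6.1 to 93.1 ± 30 TPM (2.17 ± 0.32, adjusted p = 0.00267) and Ccnb2 from 2.20 ± 0.88 to 9.59 ± 2.8 TPM (1.73 ± 0.27, adjusted p = 0.00395). Both calls ended in a fit of the 2 groups alone (adjusted p = 0.059 and 0.0907), and that of Ccnb2 on TPM as deposited (0.233). Amino acid transport and ATF4 target genes fell, 3 of 25 (14 adjusted over the list alone), with a median of -0.63, or -0.18 on TPM as deposited (preset adjusted p = 8.25e-07, 0.437 with an estimated correlation). Trib3, an ATF4-induced pseudokinase, was at -1.32 ± 0.26 (adjusted p = 0.0191), a call that ended without B220-2NBDG+ replicate 1 or 2 or BMPC replicate 1 or 2 (0.0594 to 0.103). Genes of the unfolded protein response fell, 2 of 35 (5 adjusted over the list alone), with a median of -0.42, or -0.10 on TPM as deposited (preset adjusted p = 7.15e-05, 0.602 with an estimated correlation). N-glycosylation genes fell, 2 of 41 (1 up and 8 down adjusted over the list alone), with a median of -0.30, or -0.01 on TPM as deposited (preset adjusted p = 0.00125, 0.52 with an estimated correlation). MHC class II genes fell, 1 of 11 (5 adjusted over the list alone), with a median of -0.80, or -0.28 on TPM as deposited (preset adjusted p = 6.03e-04, 0.526 with an estimated correlation). Secretory transport genes had a lower median on the main scale (-0.29) but not on TPM as deposited (0.01). Of them 1 of 45 fell, 3 adjusted over the list alone (preset adjusted p = 3.37e-05, 0.52 with an estimated correlation). On that scale this list (adjusted p = 0.144) and N-glycosylation (0.0896) were not called.

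Glycolysis genes had a higher median in the bone marrow libraries, where neutrophil markers rose too (0.22, or 0.23 on TPM as deposited; preset adjusted p = 0.0012, 0.349 with an estimated correlation). The 2 called members of 25 fell (1 rose and 2 fell adjusted over the list alone). They encode phosphofructokinase isoforms: Pfkp (-1.21 ± 0.24, adjusted p = 0.0188) and Pfkl (-0.88 ± 0.20, adjusted p = 0.0391). Both calls ended without B220-2NBDG+ replicate 1 or 3 or BMPC replicate 1 or 2, and that of Pfkl also without B220-2NBDG+ replicate 2 (adjusted p from 0.0572 to 0.147), as they did on TPM as deposited (0.0601 and 0.665). NK cell markers had a median of 0.69, or 0.14 on TPM as deposited, with 0 of 6 called, or 2 higher adjusted over the list alone (preset adjusted p = 6.25e-04, 0.0583 with an estimated correlation). Ribosomal protein genes had a median of 0.02, with 0 of 41 called by either count (preset adjusted p = 0.00236, 0.795 with an estimated correlation). Mitochondrially encoded genes had a median of 0.05, with 1 of 13 called higher by both counts (preset adjusted p = 0.00852, 0.73 with an estimated correlation). The ribosomal call ended without B220-2NBDG+ replicate 1 (0.252) or BMPC replicate 1 (0.242), and the mitochondrial call without B220-2NBDG+ replicate 2 (0.0501) or BMPC replicate 1 (0.103). Plasma cell identity genes (adjusted p = 0.469), with Tnfrsf17 at -0.11 ± 0.14 and Jchain at 0.32 ± 0.15, were not called. Nor were B cell identity (0.282), MYC targets (0.711), cholesterol biosynthesis (0.0653), autophagy and lysosome (0.481), the TCA cycle (0.986), oxidative phosphorylation (0.818) and fatty acid oxidation (0.511). The same held for markers of T cells (adjusted p = 0.0652), monocytes, macrophages and dendritic cells (0.202), erythroid cells (0.579), megakaryocytes (0.793), mast cells, basophils and eosinophils (0.435) or stroma (0.818). T cell markers were called without B220-2NBDG+ replicate 2 (0.0185) or BMPC replicate 3 (0.00894). Monocyte and related markers were called without B220-2NBDG+ replicate 3 (0.00477) or BMPC replicate 2 (0.0252), erythroid markers without B220-2NBDG+ replicate 3 (0.00512), and cholesterol biosynthesis without BMPC replicate 3 (0.0356). In 10 of the 31 lists, none called, median, mean and test differed in sign.

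**Figure D5:**
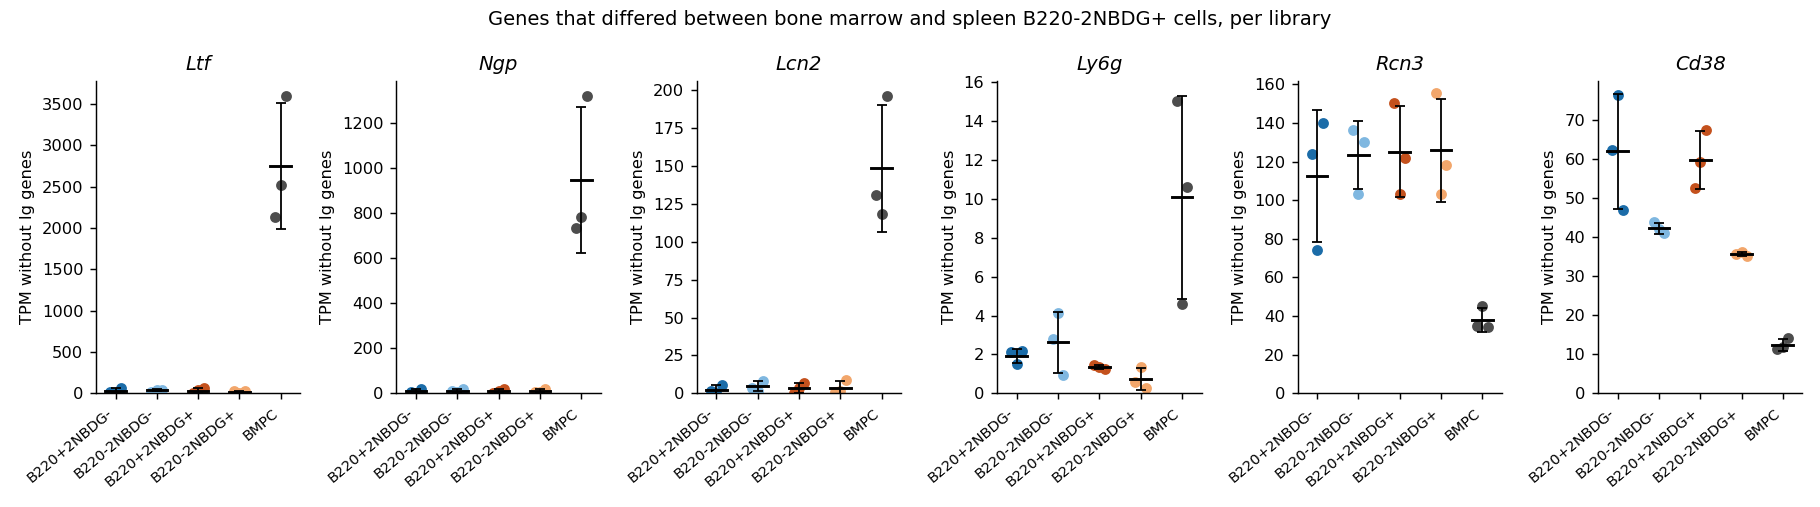
TPM without immunoglobulin genes (y axes, from 0) of 6 genes in the 5 groups (x axis), with 1 point per library and bars for the mean and SD. Ltf averages 2750 TPM and Ly6g 10.1 TPM in bone marrow against 19.1 and 0.739 TPM in spleen B220-2NBDG+, while Rcn3 and Cd38 are lower in bone marrow at 38.1 and 12.5 TPM.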

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

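Of the tests below, that for reads assigned among copies of a gene family and the splits of samples were chosen after the result was seen, while that for genomic DNA was written before its value was computed, though 1 of its 1465 genes had been seen to be higher.

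A different 2NBDG effect in B220- and B220+ cells was called for 3 genes and 3 gene lists. Each list call was lost with an estimated correlation (adjusted p = 0.987). For the gene count chance cannot be excluded, as the splits below cannot test it. The differences, B220- minus B220+, were -2.02 for Trav6n-6 (adjusted p = 0.00269), -1.86 for Mapt and -1.77 for Gm3183 (adjusted p = 0.0222 each) on the log2 scale, from limma on 3 libraries per group. With a pseudocount of 0.1 none of the 3 was called (0.291 for Trav6n-6, 0.399 for Mapt and 0.291 for Gm3183), nor with the silent-gene background subtracted (0.051, 0.311 and 0.534) or with voom (0.957, 0.989 and 0.137). Mapt and Gm3183 were not called either with only the compared groups in the fit (0.0793 each). The Mapt call also ended without B220+2NBDG- replicate 1 (0.101) or 2 (0.0957), B220+2NBDG+ replicate 1, 2 or 3 (0.0968, 0.0642 and 0.0997) or B220-2NBDG+ replicate 1, 2 or 3 (0.0729, 0.106 and 0.0876). The Gm3183 call ended without B220+2NBDG- replicate 1 (0.101) or 2 (0.0957), B220-2NBDG- replicate 1, 2 or 3 (0.0601, 0.0545 and 0.0572), B220+2NBDG+ replicate 1 (0.0968) or 3 (0.0997) or B220-2NBDG+ replicate 2 (0.106) or 3 (0.11).

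The lists were amino acid transport and ATF4 targets (adjusted p = 0.008, median -0.35), cytosolic ribosomal proteins (adjusted p = 1.77e-19, median 0.31) and monocyte, macrophage and dendritic cell markers (adjusted p = 0.008, median -1.32), none with a called member over all genes or adjusted over the list alone. Over the alternatives the adjusted p of these lists ran from 2.32e-06, 1.69e-24 and 1.91e-07 to 0.987. The call for amino acid transport ended without B220+2NBDG- replicate 1 (0.0768) or 2 (0.287), B220-2NBDG- replicate 1 (0.059) or B220-2NBDG+ replicate 2 (0.123), and that for monocyte markers without B220+2NBDG- replicate 1 (0.186), B220-2NBDG- replicate 3 (0.233), B220+2NBDG+ replicate 3 (0.414) or B220-2NBDG+ replicate 1 (0.405), or without a filter (0.106). The other 28 lists had adjusted p from 0.0898 to 0.98, and in 9 lists, none called, median, mean and test differed in sign. Of 100 splits of the 12 spleen libraries, 6, the real one included, called at least 3 genes. The highest other called 94 and exchanged replicate 3 of B220+2NBDG- with replicate 3 of B220+2NBDG+. This weakens the 2NBDG effect in B220+ cells alone, which can pass for an interaction, so the splits cannot decide on chance.

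The interaction genes were higher in the same B220-2NBDG- libraries as the 12 satellite-like Gm genes. Reads moved among near-identical copies would leave the family's sum alike between groups, but that sum was 5.82 times as high in B220-2NBDG- as in the next group. Reads from genomic DNA are a candidate source, since reads on silent olfactory and vomeronasal receptor genes then rise too, and their share of reads was 2.58 times as high there as in the next group. Genomic DNA therefore stays open for the Gm genes, and a biological difference of these cells also stays open and was not tested.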

How the results depend on the processing

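The voom, background, estimated-read and correlation leave-out tests were chosen after the result was seen. With 3 libraries per group the gene test recovered 49.3% of simulated changes by a factor of 2 in bone marrow. In the interaction it recovered 9% of these, so most changes by a factor of 2 or less would be missed there. Values kept their direction and side of the threshold unless named or counted in these documents. For the others the cause was not tested, but a smaller fit has fewer residual degrees of freedom and each leave-out fewer samples. TPM as deposited keeps the immunoglobulin share in the total and is shrunk more by the pseudocount of 1. The immunoglobulin shares kept their calls without any 1 library and as shares of estimated reads, and from constant genes alone were 0.47 (exact permutation p = 0.065) and 0.20 points (exact permutation p = 0.42) for averaged 2NBDG and B220.

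On TPM as deposited the counts were 8286 (2NBDG averaged), 7427 (2NBDG within B220+), 2632 (2NBDG within B220-), 6861 (B220 averaged), 6415 (B220 within 2NBDG-), 80 (interaction) and 100 (bone marrow). Without a filter they were 141 (2NBDG within B220+), 764 (2NBDG within B220-), 1046 (B220 within 2NBDG-) and 26 (interaction). The replicate block gave 485 (2NBDG within B220+), 228 (B220 within 2NBDG+) and 335 (bone marrow, where the numbers do not mark pairs). With only the compared groups in the fit they were 5 and 159 (2NBDG within B220+ and within B220-), 38 and 118 (B220 within 2NBDG+ and within 2NBDG-) and 53 (bone marrow). With limma-voom on estimated reads they were 423 (2NBDG within B220+), 992 (B220 within 2NBDG-), 0 (interaction) and 138 (bone marrow). The interaction also gave 0 with a pseudocount of 0.1, with background subtracted and on transcripts. Genes with a called transcript numbered 370, 35 and 119 for 2NBDG (averaged, within B220+ and within B220-), 572, 77 and 297 for B220 (averaged, within 2NBDG+ and within 2NBDG-) and 98 for bone marrow. Leaving out 1 library gave 458 to 1163, 29 to 376 and 125 to 289 calls for 2NBDG, 569 to 1339, 56 to 122 and 229 to 682 for B220, 1 to 4 for the interaction and 88 to 297 for bone marrow.

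The correlations of effects (2NBDG across strata, B220 across strata, and 2NBDG with B220) were 0.713, 0.679 and 0.711 on TPM as deposited and 0.418, 0.385 and 0.317 with a pseudocount of 0.1, and the last was 0.323 without a filter. Leaving out 1 library gave 0.368 to 0.501, 0.354 to 0.483 and 0.262 to 0.479.

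On TPM as deposited these named genes turned from positive to negative with 2NBDG: Ndufs7 (-0.41), mt-Atp6 (-0.59), Eci1 (-0.086), Fut8 (-0.19), Sil1 (-0.27), Ssr4 (-0.28), Pycr1 (-0.060), Ctsb (-0.065), Cd81 (-0.27), Bst2 (-0.014), Gpx4 (-0.12), Slc2a1 (-0.28), Prdm1 (-0.45) and Xbp1 (-0.49). With loss of B220 those were Ndufa1 (-0.47), Cox4i1 (-0.44), Etfb (-0.48), Hadhb (-0.39), Sil1 (-0.017), Gpx4 (-0.017), Tcf4 (-0.37) and Xbp1 (-0.43). Mapt turned positive in the interaction with voom (0.31). Lists that turned on TPM as deposited, with their adjusted p there, were oxidative phosphorylation (7.45e-05), mitochondrially encoded genes (0.737), fatty acid oxidation (0.538), N-glycosylation (0.0179), secretory transport (2.02e-05) and oxidative stress defence (0.523) for 2NBDG, oxidative phosphorylation (0.00267) and mitochondrially encoded genes (0.647) for B220, and cell cycle (9.25e-13) and neutrophil markers (0.00436) for the interaction.

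Other lists also crossed the threshold (adjusted p in brackets). For 2NBDG, calls ended for MYC targets (0.128) and B cell identity (0.172) without a filter, and for erythroid markers with median-of-ratios scaling (0.0834) or background subtracted (0.0906). That for mast cell markers ended with median-of-ratios scaling (0.0653), a pseudocount of 0.1 (0.0595), no filter (0.11) or background subtracted (0.0621). The interferon list was called on TPM as deposited (0.00607), without a filter (0.00606) and with the replicate block (0.0305).

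For B220, calls ended without a filter for mitochondrially encoded genes (0.202) and neutrophil markers (0.097), the latter also with median-of-ratios scaling (0.0625). On TPM as deposited the ribosomal (2.71e-05), monocyte (0.0318), erythroid (0.00152), mast cell (0.0464) and stromal lists (0.0124) were called. Without a filter these were ribosomal proteins (3.33e-04) and homing (0.0142). Autophagy was called with median-of-ratios scaling (0.0349) and with background subtracted (0.0231).

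In the interaction, lists called under at least 1 setting or leave-out were oxidative phosphorylation (0.0216 to 0.0487), mitochondrially encoded genes (5.92e-04 to 0.0484), the unfolded protein response (2.32e-06 to 0.0413), autophagy (0.0264 to 0.0451), cell cycle (9.25e-13 to 0.0255), interferon (1.76e-04 to 0.0285) and erythroid markers (1.76e-04 to 0.0427). Without B220+2NBDG- replicate 3 these also included B cell identity (0.00392), MHC class II (0.0279), plasma cell identity (0.0268) and T cell markers (0.00384), and on TPM as deposited mast cell markers (0.0221).

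In bone marrow, oxidative phosphorylation (1.52e-04 and 0.00607), cholesterol biosynthesis (0.0359 and 0.0157), immediate early genes (0.0337 and 0.0153) and oxidative stress defence (0.00215 and 0.012) were called on TPM as deposited and with median-of-ratios scaling, and interferon (0.0359) on TPM as deposited. Without a filter B cell identity (0.0312), immediate early genes (0.0312) and mast cell markers (0.00167) were called.

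Among genes named in the report, Ldha and Pgk1 lost their 2NBDG calls with median-of-ratios scaling (0.101 and 0.076), and Ldha also with only the compared groups (0.0629) and with voom (0.0523), which ended the Cd81 call too (0.0556). In bone marrow Trib3 lost its call on TPM as deposited (0.361), with only the compared groups (0.109) and with voom (0.0509), and S100a8 without a filter (0.0851) and with only the compared groups (0.0603). Pfkp lost its call with only the compared groups (0.145), and Pfkl with these (0.0789), with median-of-ratios scaling (0.0872), without a filter (0.0613) and with voom (0.0952). Adamdec1, Rgs1, Dgkg, Josd2, Frmpd2 and Cox6a2 lost theirs under 1 to 5 settings each (0.0525 to 0.775).

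Of 173 called named results, 42 lost their call on TPM as deposited besides 12 that turned, 50 with median-of-ratios scaling, 49 with only the compared groups, 44 without a filter, 36 with voom, 8 with background subtracted, 7 with a pseudocount of 0.1, 3 with the replicate block and 87 without at least 1 library. Of 90 that were not called, 10, 2, 0, 3, 1, 2, 1, 5 and 4 were called with the same sign under these settings in the same order. On TPM as deposited 10 others were called with the opposite sign.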

Other observations

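Of the tests below, those for a general rise of other cell types and for scaling, and all splits of the samples, were chosen after the result was seen. Those with the second neutrophil list and without the B220+2NBDG- libraries were chosen after values of 5 of its genes and of 12 cell cycle genes were seen, and that without replicate 3 was written before.

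On the main scale the homing and survival lists were not called. With loss of B220, the chemokine receptor Cxcr3 fell by -1.59 ± 0.12 (log2 ± SE, adjusted p = 6.44e-05; ENSMUSG00000050232.6, chromosome X, 101731535 to 101734269), from 93.5 ± 6.5 and 76.3 ± 5.9 TPM in B220+2NBDG- and B220+2NBDG+ to 35.1 ± 6.7 and 21.6 ± 1.7 TPM in B220-2NBDG- and B220-2NBDG+ (SD, n = 3 each, limma). The S1P receptor S1pr1, used in exit from tissue, fell by -1.38 ± 0.33 (adjusted p = 0.0196, and 0.0568 without B220+2NBDG+ replicate 2). Of the 33 genes of the homing list, 2 rose and 5 fell with loss of B220 (5 and 9 adjusted over the list alone; adjusted p = 0.522), 1 rose and 1 fell with 2NBDG (6 and 6 adjusted over the list alone; adjusted p = 0.928), and 2 fell in bone marrow (2 adjusted over the list alone; adjusted p = 0.469). The tetraspanin Cd81 rose with 2NBDG by 0.43 ± 0.08 (adjusted p = 0.00618) on the main scale and fell by -0.27 on TPM as deposited (adjusted p = 0.0478). The BCL2 family list was not called with 2NBDG (adjusted p = 0.928, with 2 of 24 members lower), with B220 (0.884, with 3 lower) or in bone marrow (0.818). Nor was the NF-kappaB list (0.997, 0.912 and 0.818), of which Nfkb1 fell by -0.70 ± 0.13 with loss of B220 (adjusted p = 0.00553).

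The immediate early list was not called (adjusted p = 0.997 with 2NBDG, 0.754 with B220 and 0.0794 in bone marrow), though it was called in bone marrow without B220-2NBDG+ replicate 1 (0.0295) or BMPC replicate 2 (0.0183), and its member Dusp2, a phosphatase, fell by -1.15 ± 0.22 with loss of B220 (adjusted p = 0.00582). The interferon list (0.0671, 0.884 and 0.439) was called with 2NBDG without B220+2NBDG- replicate 2 (0.0342), B220-2NBDG- replicate 3 (0.00224), B220+2NBDG+ replicate 1 (0.00783) or 2 (0.0121) or B220-2NBDG+ replicate 1 (0.00502) or 2 (0.0305), and in bone marrow without B220-2NBDG+ replicate 1 (0.0137). Its member Bst2 rose with 2NBDG by 0.69 ± 0.14 (adjusted p = 0.012) on the main scale and was at -0.014 on TPM as deposited. Oxidative stress genes were not called with B220 (adjusted p = 0.929) or in bone marrow (0.202).

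Neutrophil genes were higher in the bone marrow libraries although Ly6g-positive cells were gated out. A general rise of RNA from every other cell type would lift their markers alike, but the lowest of 4 other list medians was -0.64 (megakaryocyte markers), with T cell markers at -0.15, monocyte and macrophage markers at -0.18 and erythroid markers at -0.09. NK cell markers, outside these 4 lists, had a median of 0.69 with 0 of 6 members called (adjusted p = 0.0583 with an estimated correlation). RNA from neutrophils or their precursors is a candidate source: a second list of 27 other neutrophil genes, 23 of them tested, had a median log2 fold change of 1.12, with 19 higher and 9 called higher. Without the 5 genes seen before it was written, the median of the other 18 was 1.03, with 14 higher and 4 called higher. Expression of these genes by the bone marrow plasma cells themselves stays open and was not tested.

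Cell cycle genes were lower in the 2NBDG+ and in the B220- spleen subsets. Scaling would move them with all genes, but with median-of-ratios scaling their median lay -1.15 (2NBDG) and -1.25 (B220) from that of all genes. On TPM as deposited, shrunk by the pseudocount, it lay -0.51 and -0.545 off, just past the set bound of -0.5. Without replicate 3 of B220+2NBDG- the higher of the 2 medians was -1.18. In comparisons without any B220+2NBDG- library it was -1.32, and -1.06 over the 32 members not seen before. Scaling, that replicate and T or B cell RNA of those libraries alone were therefore excluded as the whole cause. Such RNA stays open in other groups. In B220-2NBDG+ T cell markers (2.07) lay below B220-2NBDG- (3.25), and B cell genes (4.59) below B220+2NBDG+ (5.40), as log2 means. Fewer dividing cells may also account for the fall, a hypothesis found on these libraries and not tested.

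Other splits of the samples were fitted in the same way. For averaged 2NBDG, 1 of 100 splits, the real one, gave 726 calls and the highest other gave 4, so chance can be excluded. Among all 32 splits that part the 6 same-number pairs, the real one alone gave as many, and the highest other, which exchanged replicate 3 of the B220+ groups, gave 94. For averaged B220, 1 of 100 gave 973 and the highest other 169, so chance can be excluded there too. That other split exchanged only B220+2NBDG+ replicate 1 with B220-2NBDG+ replicate 3, so its calls can come from the real contrast of the other libraries. Among all 32 splits that part the 6 pairs, the real one alone gave 973 and the highest other 61. The 10 splits for 3 against 3 libraries are too few for a share under 0.05. There the real split was the 1 with the most calls each time: 247 against 3 for the highest other (2NBDG within B220+), 314 against 1 (2NBDG within B220-), 151 against 1 (B220 within 2NBDG+), 589 against 5 (B220 within 2NBDG-) and 216 against 1 (bone marrow).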
